A study of Homo sapiens with 8 samples.

How the data were processed

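Total RNA of 8 samples, 2 for each of 4 groups (A2780 or SKOV3 cells at 37 °C or 46 °C), had been labelled with biotin and hybridised to Illumina BeadChips of 47231 probes. The deposited signal table holds the linear probe intensity of each array as exported by the authors with BeadStudio, whose version the labels do not give. Its intensities are not normalized between arrays and not background-subtracted, and it has no detection p-values. A table of log2 values processed by the authors covers the same arrays. Its columns share 1 distribution and keep the order of the signals within each array (rank correlation 1), and they lie within 0.025 of a quantile normalization of the log2 signals, but the labels do not describe these steps.

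The signals were background-corrected with the normexp method of limma 3.58.1 in R 4.3.3 with an offset of 50, quantile-normalized and expressed on the log2 scale. Probes were named from the platform's annotation: 30113 carried 1 gene symbol, 8 carried several and 17110 were not listed. Gene identifiers of 30074 of the 30121 listed probes were found in the reference table of gene names. Probes with a mean log2 value above the 40th percentile (6.16) were kept, 28338 in all. Of the 19547 with 1 symbol, the probe with the highest mean stood for its gene, which left 14190 genes, 4032 of them with more than 1 probe. The 8791 kept probes without a single symbol were not part of the comparisons. Gene classes and genomic spans came from a RefSeq table on GRCh38.p14; the files name no genome build, so no coordinates are given. Of the genes with several probes that were called, all probes had the same sign for 138 of 177 in A2780 and 96 of 130 in SKOV3. No columns of the tables were left unused.

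Background on each array was estimated from its own signals. The level was the 99th percentile of a normal distribution centred on the mode of the log2 signals, with its spread taken from the values below the mode. Where a group had no sample above background, the fold is given as a lower bound against that level. Array medians and the share of probes above background describe the depth; with 2 arrays per group their number limits the precision.

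A linear model with 4 groups was fitted to all 8 arrays with limma and moderated by empirical Bayes (4 residual and 9.4 prior degrees of freedom). The comparisons were the response to 46 °C in each line, the difference between these responses, and the lines at 37 °C. An additive model with line and temperature gave the response common to both, which is the change averaged over the lines. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 14190 genes, with a threshold of 0.05. The fits and their alternatives, the lists and the rule for named genes were set before the data were examined. The replicate numbers were not treated as pairs; the deviations of equally numbered samples from their group means correlated across genes at 0.072 in A2780 and -0.25 in SKOV3. Between the lines these correlations were 0.291 for the hyperthermia groups, 0.175 for the control groups, and -0.254 and -0.071 for a control group of one line with the hyperthermia group of the other.

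Of 34 gene lists, 33 had at least 5 tested members and were tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation, with p-values adjusted over the lists; the list of endothelial markers had 3 tested members and was left out. A label check and a gene list that passed between the lines at 37 °C are not reported here. The rule for named genes took, among genes past the test whose values did not overlap between the groups, the 10 largest rises and falls in each line and between the lines, 6 in each direction for the difference and 5 for the common response, and up to 4 members of each list described. It also named ERBB2, HSPA1A, HSPA1B and DNAJB1 as checks of the labels, and passed over genes known only by a clone or LOC number.

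The alternatives were the authors' log2 values, a floor of 16 with no background correction, median scaling, no between-array normalization, no filter, a filter at the 60th percentile, a trended and robust prior, a minimum change of 2-fold, the replicate number as a block, array weights, only the arrays of a comparison, the mean of both lines' contrasts for the common response, the estimated correlation, other probes of a gene, and leaving out each array in turn. Chosen after seeing the data were a filter on background, the inclusion of probes without a gene name, a block with the SKOV3 hyperthermia numbers crossed, and median scaling without A2780 control 2. Normexp with offset 50 on the signal alone, first listed as an alternative, is the procedure used here and was not run again. The lists were not tested with the trended prior or the 2-fold minimum.

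The procedure from the linear model onward was tested on simulated normalized values of 14190 genes, of which 200 were changed. At a log2 change of 0.5, 1 and 2 it called 47.8%, 100% and 100% of the changed genes in A2780, 47.8%, 98.5% and 100% in SKOV3 and 88.1%, 100% and 100% in the common response. It made 16 false calls among 181 in A2780, 16 among 180 in SKOV3 and 18 among 210 in the common response, and none in the difference, where nothing had been changed. No list was called when none was shifted, and a list shifted by 0.5 was called by camera with an adjusted p of 9.96e-33. The simulated noise was independent between genes, so false calls of lists among correlated genes were not tested. Background correction, normalization and filtering were not part of the simulation.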

Results

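Transcript levels were measured on Illumina BeadChips in cells labelled as A2780 and SKOV3, both established human ovarian cancer lines, at 37 °C (control) and at 46 °C (hyperthermia). Each of the 4 groups held 2 samples, so 8 arrays were compared. The median probe signal per array ran from 114 to 144. Between 37.6% and 39.8% of the probes lay above background on each array except A2780 control 2, where 43.7% did. That array was also the brightest, with an upper quartile of 317 against 181 to 243 on the others. The number of arrays limits the precision of every value. The labels do not give the length of the exposure or the time of collection, nor whether the samples of a group came from separate cultures. The p-values set each change against the spread between these samples, moderated across genes. Whether a change would repeat in further cultures was therefore not tested. Changes are differences of normalized log2 intensity, followed after ± by their SE from the limma fit (n = 2 per group), and levels are group means on the same scale. A gene rose or fell where its adjusted p passed the threshold of 0.05.

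The first comparison asked how 46 °C changed transcripts in A2780. Heat-shock genes rose most. HSPA6, a strictly heat-inducible HSP70, went from 6.56 to 13.82 (7.26 ± 0.14, adjusted p = 3.65e-13). HSPA1A, the major inducible HSP70, was not above background at 37 °C and was at least 103-fold higher at 46 °C (6.99 ± 0.12, adjusted p = 3.52e-13). HSPA7, a close relative of HSPA6 that may share its probe signal, rose by 6.60 ± 0.15. RNAs that are not translated rose too: RN7SK, the 7SK RNA that restrains transcription elongation, rose by 5.89 ± 0.13, RNA5S9, a 5S ribosomal RNA, by 5.50 ± 0.13, and RNU6ATAC, a minor spliceosome RNA, by 4.43 ± 0.14. The immediate early transcription factors FOS (5.43 ± 0.13), EGR1 (4.53 ± 0.13) and JUN (4.38 ± 0.13, at least 15.96-fold) rose as well, as did RIMBP3 (4.38 ± 0.14), whose other probe changed by 0.39 with an adjusted p of 0.232. The adjusted p of these 10 genes was at most 1.23e-10. Falls were smaller. SNORA12, a small nucleolar RNA, fell by 1.85 ± 0.18, FAM110D by 1.58 ± 0.14, the nuclear matrix protein gene BANP by 1.48 ± 0.13, CCDC71 by 1.47 ± 0.18, the Wnt antagonist DKK1 by 1.47 ± 0.12, and ID1, an inhibitor of helix-loop-helix transcription factors, by 1.41 ± 0.16. GEMIN4, of the SMN complex, fell by 1.39 ± 0.13, HPS6 by 1.22 ± 0.14, D2HGDH, a D-2-hydroxyglutarate dehydrogenase, by 1.20 ± 0.13, and MARS2, the mitochondrial methionyl-tRNA synthetase, by 1.18 ± 0.12. The adjusted p of these 10 genes was at most 0.000152. Other probes of BANP gave -0.46 (adjusted p = 0.131) and -0.85, another probe of D2HGDH gave 0.057, and another probe of ID1 gave -0.17.

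Among gene lists fixed beforehand, immediate early genes changed most in A2780: 17 of 31 rose and none fell (18 and 2 when adjusted over the list alone), with an adjusted p of 6.03e-24 for the list. FOS, EGR1, JUN and FOSB (3.51 ± 0.17) led them. Of 28 cytosolic heat-shock chaperones, 13 rose and none fell (16 and 0 adjusted over the list alone; list adjusted p = 1.3e-19), among them HSPA1B (3.11 ± 0.13) and the HSP40 gene DNAJB1 (2.89 ± 0.13). Both lists also passed with an estimated correlation between genes (adjusted p = 0.0293 and 0.015). The other lists that passed in A2780 did so only with the preset correlation. Of 21 targets of ATF4 and the integrated stress response, 6 rose and none fell (8 and 0 adjusted over the list alone; list adjusted p = 7.19e-06, and adjusted p = 0.144 with an estimated correlation): PPP1R15A, which directs a phosphatase to eIF2α, rose by 3.27 ± 0.14, the secreted glycoprotein gene STC2 by 2.03 ± 0.14, the glutathione-degrading enzyme gene CHAC1 by 2.02 ± 0.16 and the transcription factor gene ATF3 by 1.13 ± 0.13. Of 21 replication-dependent histone genes, whose near-identical copies share probe signal, 7 rose and none fell (11 and 0 adjusted over the list alone; list adjusted p = 3.11e-07, and adjusted p = 0.357 with an estimated correlation), with H4C8 at 0.94 ± 0.15, H2BC21 at 0.89 ± 0.13, H2AC17 at 0.82 ± 0.13 and H2AC18 at 0.67 ± 0.13. Among 8 leukocyte markers 1 rose, CD14, a co-receptor for lipopolysaccharide, by 2.90 ± 0.13 (4 and 0 adjusted over the list alone; list adjusted p = 0.00105, and adjusted p = 0.144 with an estimated correlation). Of the 391 zinc finger genes, 26 fell and 7 rose (33 and 12 adjusted over the list alone; list adjusted p = 0.029, and adjusted p = 0.5 with an estimated correlation). ZNF114 fell by 0.99 ± 0.13 and ZNF791 by 0.87 ± 0.18, while ZNF280A rose by 0.86 ± 0.15 and ZNF626 by 0.83 ± 0.15, although another probe of ZNF626 gave -0.17. The zinc finger list lost its call without A2780 control 1 (adjusted p = 0.567) and without A2780 hyperthermia 2 (adjusted p = 0.0834), in a range of 0.00074 to 0.567 over all its alternatives. It also lost it with the authors' values (0.0576), the floor (0.0559), median scaling (0.0804), no between-array normalization (0.0775) and the stricter filter (0.0526).

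The remaining 27 lists did not pass in A2780 (adjusted p from 0.0981 to 0.987), though single members changed. Of 16 ER chaperones, HSPA5 (BiP) rose by 1.78 ± 0.15 and DNAJB9 by 0.91 ± 0.19, and EDEM1 fell by 0.49 ± 0.13. Of 14 TGF-beta and BMP targets, 4 rose and 2 fell: ID1 and ID3 (-1.11 ± 0.15) fell, and HEY1 (0.86 ± 0.15) and BAMBI (0.82 ± 0.15) were among those that rose. The vasodilator peptide gene ADM, alone among 22 hypoxia and glycolysis genes, rose by 2.45 ± 0.15, ZFAND2A, a stress-induced partner of the proteasome, by 1.38 ± 0.14, and HMOX1, heme oxygenase, by 0.95 ± 0.14. HBA2, an alpha globin gene, was not above background at 37 °C and rose by 0.99 ± 0.12 (at least 1.80-fold). The calls of BAMBI (adjusted p = 0.0578 and 0.0998), DNAJB9 (0.123 and 0.0667) and ZNF626 (0.0521 and 0.0771) were lost without A2780 control 2 and without A2780 hyperthermia 1, and that of DNAJB9 also without A2780 hyperthermia 2 (0.126). The call of H2AC18 was lost without A2780 hyperthermia 1 (0.0965) or hyperthermia 2 (0.0733), those of HEY1 (0.0504) and ZNF280A (0.0766) without hyperthermia 1, and that of ZNF791 (0.161) without hyperthermia 2. EDEM1 lost its call without any 1 of the A2780 arrays or either SKOV3 control array (adjusted p = 0.0881 to 0.232), and also with the replicate number as a block (0.0618), with a trended and robust prior (0.0745) and with the A2780 arrays alone (0.0713). Other probes of H2AC18 (0.439), HEY1 (0.087) and ZNF626 (0.145) changed less and did not pass. Over all alternatives the adjusted p ran from 0.00275 to 0.298 for BAMBI, 0.00117 to 0.224 for DNAJB9, 0.000452 to 0.232 for EDEM1, 0.00504 to 0.786 for H2AC18, 0.000913 to 0.869 for HEY1, 0.00164 to 0.142 for ZNF280A, 0.00261 to 0.706 for ZNF626 and 6.54e-05 to 0.161 for ZNF791.

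In all, 319 of 14190 genes were higher and 331 lower at 46 °C in A2780, of which 112 and 29 changed at least 2-fold. An unadjusted p under 0.05 was reached by 2564 genes, against 710 by chance. The count was 1146 without A2780 control 1, 321 without A2780 control 2, 242 without A2780 hyperthermia 1 and 269 without A2780 hyperthermia 2. Quantile normalization fixes the balance of rises and falls: with median scaling the median of all genes was -0.28 and 189 genes were higher and 4395 lower, and with no between-array normalization it was -0.385, with 128 higher and 5183 lower. The changes given here are therefore relative to the median gene. Under these scalings the median of the ATF4 targets was -0.114 and -0.219, but 0.166 above that of all genes under both, and the calls of BAMBI, DNAJB9, H2AC18, HEY1, HMOX1 and ZNF626 were lost. With no between-array normalization those of H4C8 (adjusted p = 0.0693), H2BC21 (0.107), H2AC17 (0.0597) and ZNF280A (0.142) were lost as well. No named histone gene kept its call there (ranges over all alternatives 0.000488 to 0.0693 for H4C8, 0.000411 to 0.107 for H2BC21 and 0.00101 to 0.0597 for H2AC17).

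The same question in SKOV3 gave much the same leading genes. HSPA6 went from 6.58 to 13.71 (7.14 ± 0.14, adjusted p = 9.17e-13). HSPA1A, again not above background at 37 °C, was at least 62.1-fold higher (6.11 ± 0.12), and HSPA7 rose by 6.11 ± 0.15. RNA5S9 rose by 5.68 ± 0.13 and RN7SK by 5.61 ± 0.13. RMRP, the RNA of RNase MRP, rose by 5.55 ± 0.16 from background (at least 37.0-fold), and RPPH1, the RNA of RNase P, by 4.69 ± 0.14. FOS rose by 5.36 ± 0.13, RNU6ATAC by 4.09 ± 0.14 and RIMBP3 by 3.97 ± 0.14, its other probe giving 0.36 (adjusted p = 0.344). The adjusted p of these 10 genes was at most 4.06e-10. ID1 fell most, by 1.93 ± 0.16, followed by the chemokine gene CXCL1 (-1.53 ± 0.19), the SMN complex gene GEMIN6 (-1.44 ± 0.13), the homeobox gene HOXB8 (-1.43 ± 0.14) and BANP (-1.28 ± 0.13, with -0.87 and -0.1 at other probes). D2HGDH (-1.28 ± 0.13, another probe -0.028), ZNF121 (-1.28 ± 0.14), FJX1 (-1.24 ± 0.13), the lipid droplet gene HILPDA (-1.20 ± 0.18) and BRINP3 (-1.16 ± 0.14) fell as well. The adjusted p of these 10 genes was at most 0.00143.

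In SKOV3, 14 of 31 immediate early genes rose and 1 fell (15 and 3 adjusted over the list alone; list adjusted p = 1.7e-18, and adjusted p = 0.0477 with an estimated correlation), with FOS, JUN (3.33 ± 0.13), EGR1 (2.96 ± 0.13) and FOSB (2.76 ± 0.17) in the lead. Of 28 cytosolic heat-shock chaperones, 8 rose and none fell (11 and 0 adjusted over the list alone; list adjusted p = 4.18e-18, and adjusted p = 0.0176 with an estimated correlation), including DNAJB1 (3.24 ± 0.13) and HSPA1B (2.63 ± 0.13). HSPA1B reached 14.07, near the highest normalized value, where a change can be compressed. The other lists that passed lost their calls with an estimated correlation. Of 21 ATF4 targets, 2 rose, PPP1R15A (3.24 ± 0.14) and ATF3 (1.15 ± 0.13), and ATF5 fell by 0.89 ± 0.15 (3 and 1 adjusted over the list alone, list adjusted p = 0.0385, and adjusted p = 0.577 with an estimated correlation). Of 16 ER chaperones, 2 rose, HSPA5 by 1.60 ± 0.15 and DNAJB9 by 1.24 ± 0.19 (3 and 1 adjusted over the list alone, list adjusted p = 0.0385, and adjusted p = 0.339 with an estimated correlation). Of 5 erythroid markers, 1 rose, HBA2, by 0.87 ± 0.12 (3 and 0 adjusted over the list alone; list adjusted p = 0.0294, and adjusted p = 0.339 with an estimated correlation), while the other HBA2 probe gave 0.26 here and 0.13 in A2780 and did not pass in either line.

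The remaining 28 lists did not pass in SKOV3 (adjusted p from 0.291 to 0.979). CD14 rose by 2.62 ± 0.13 from background (at least 5.48-fold), and the leukocyte markers had a median of -0.03 but a mean of 0.34. Of 21 histone genes none rose and 2 fell, H4C3 by 1.01 ± 0.21 and H2BC5 by 0.80 ± 0.13. Of 14 TGF-beta and BMP targets 2 rose, BAMBI (1.22 ± 0.15, at least 2.14-fold from background) and the inhibitory SMAD gene SMAD7 (0.86 ± 0.17), and 3 fell, among them ID1 and ID3 (-0.97 ± 0.15). ZFAND2A rose by 1.41 ± 0.14 and ADM by 1.35 ± 0.15. Without SKOV3 control 1 the calls of H4C3 (adjusted p = 0.216), H2BC5 (0.0654) and SMAD7 (0.188) were lost, as were those of H4C3 (0.0554), SMAD7 (0.0586) and ATF5 (0.06) without SKOV3 control 2, of SMAD7 (0.06) without SKOV3 hyperthermia 1 and of H4C3 (0.0799) without SKOV3 hyperthermia 2. With no between-array normalization H2BC5 (0.0506) and SMAD7 (0.0669) lost theirs, and other probes of these genes gave -0.373 and 0.446 and did not pass. Over all alternatives the range was 0.000963 to 0.216 for H4C3, 0.000554 to 0.253 for H2BC5, 0.00295 to 0.188 for SMAD7 and 0.000173 to 0.06 for ATF5.

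In SKOV3, 220 genes were higher and 239 lower at 46 °C, 93 and 32 of them at least 2-fold, and 2134 genes had an unadjusted p under 0.05 (710 by chance). The count was 179 without SKOV3 control 1, 174 without SKOV3 control 2 and 284 without SKOV3 hyperthermia 2. With median scaling it was 265 (150 higher and 115 lower) and with no between-array normalization 192 (126 and 66). The number of lists that passed fell from 5 to 3 without SKOV3 control 1 and to 2 without SKOV3 hyperthermia 1. Without these arrays the adjusted p was 0.127 and 0.279 for ER chaperones and 0.197 and 0.44 for ATF4 targets, and for erythroid markers it was 0.124 without SKOV3 control 2 and 0.0612 without SKOV3 hyperthermia 1. ER chaperones and ATF4 targets also missed the threshold with the authors' values (0.0585 for each), the floor (0.0592 and 0.0593) and the stricter filter (0.0572 for each), and erythroid markers with the authors' values (0.0514). Over all alternatives it ranged from 0.00493 to 0.339 for ER chaperones, from 0.00772 to 0.577 for ATF4 targets and from 0.00972 to 0.339 for erythroid markers.

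**Figure D1:**
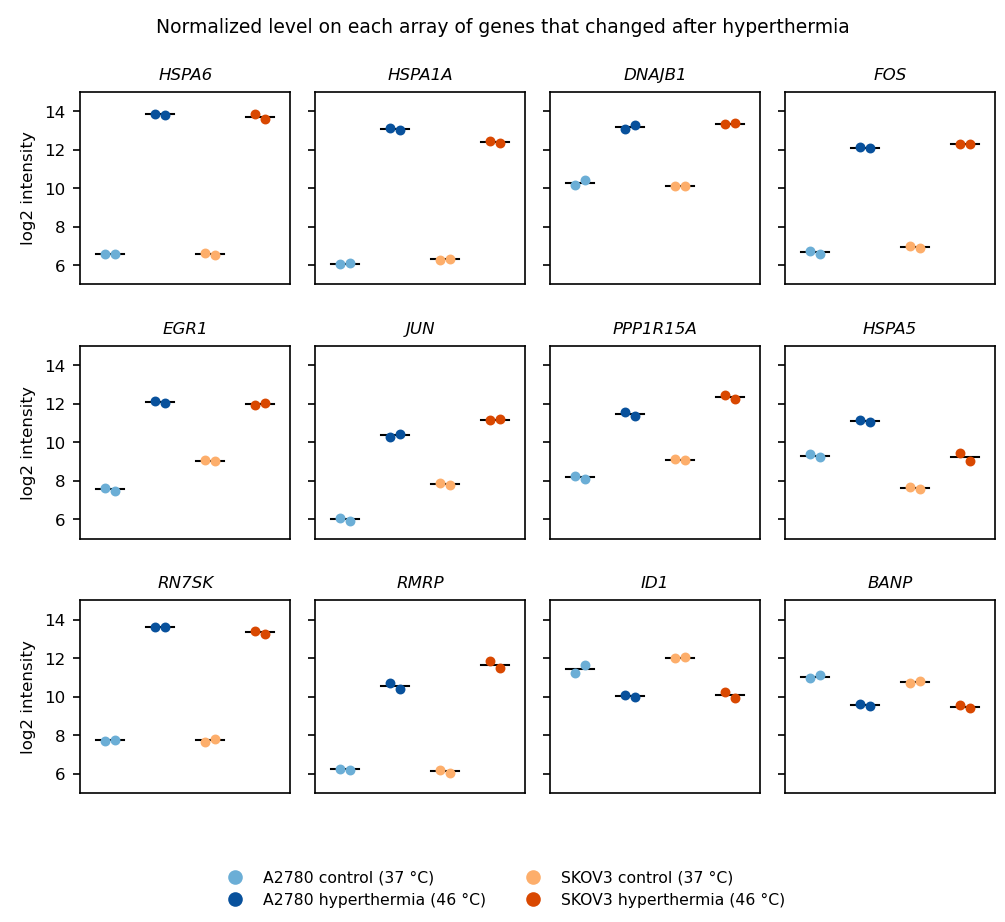
Normalized log2 intensity of 12 genes on each of the 8 arrays (points) with the group means (bars), by line and temperature. HSPA6 rose from 6.56 to 13.82 in A2780 and from 6.58 to 13.71 in SKOV3, while ID1 and BANP fell in both lines.

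**Figure D2:**
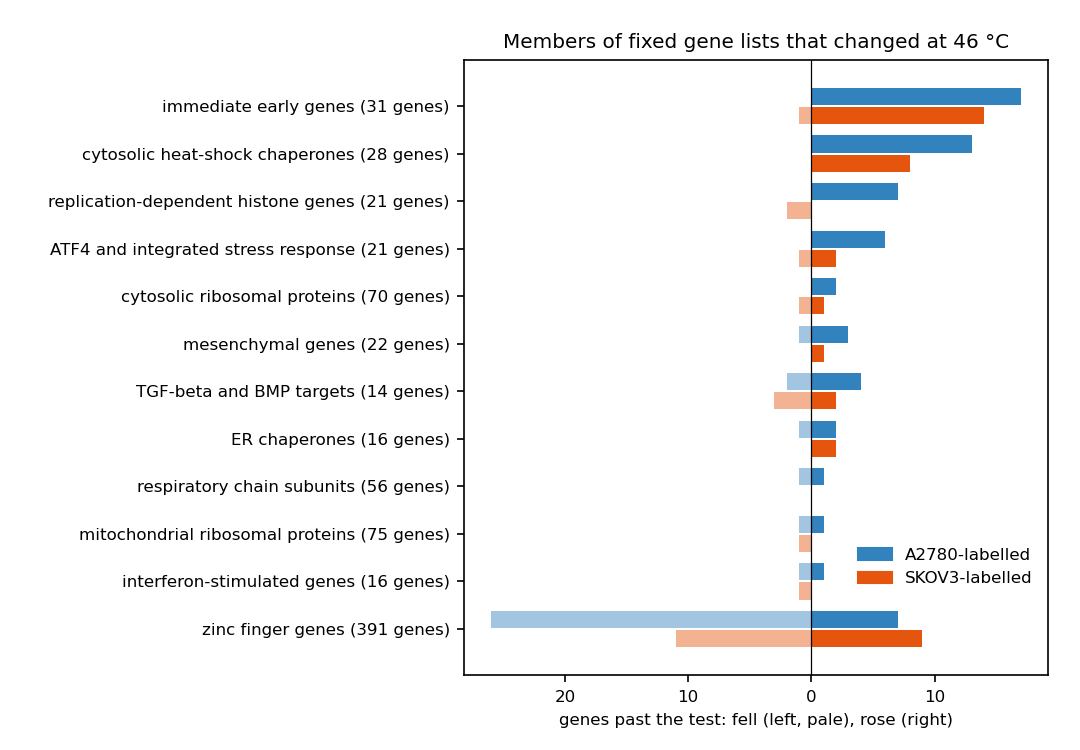
Number of members of fixed gene lists that rose (right) or fell (left, pale) at 46 °C in A2780 and SKOV3, with the number of genes tested in each list. Only lists with more than a single member past the test in either line are drawn, apart from a list that is not reported here. Immediate early genes (17 and 14 rises) and cytosolic heat-shock chaperones (13 and 8 rises) stand out in both lines. With no between-array normalization the median of the ATF4 targets in A2780 is -0.219, against -0.385 for all genes.

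The responses of the lines were compared with each other to ask what they shared. Of the genes called in each line, 148 were higher in both and 106 lower in both, against 4.9 and 5.6 expected of independent lists, and none moved in opposite directions (5.4 and 5.1 expected). The tests of both lines share 1 estimate of each gene's spread, so their calls are not independent even without a shared response. The expected counts may therefore be too low. Across all 14190 genes the log2 changes of the lines had a Pearson r of 0.654, and across the 855 genes called in either line 0.884, genes not being independent replicates. Of the 855, 773 (90.4%) had the same sign in both lines. In the fit of both lines together, the largest common rises were HSPA6 (7.20 ± 0.10, adjusted p = 4.86e-15), HSPA1A (6.55 ± 0.15, from background), HSPA7 (6.35 ± 0.12), RN7SK (5.75 ± 0.10) and RNA5S9 (5.59 ± 0.09), and the largest common falls were ID1 (-1.67 ± 0.13, adjusted p = 1.69e-06), BANP (-1.38 ± 0.10), FAM110D (-1.27 ± 0.13), D2HGDH (-1.24 ± 0.09, another probe 0.015) and GEMIN4 (-1.24 ± 0.10). That fit tests the change averaged over the lines, so a gene that moved mainly in 1 of them can pass. It called 425 genes higher and 574 lower. Without A2780 hyperthermia 2 it called 561 genes and without SKOV3 control 2 it called 620. With median scaling the split was 167 higher and 1042 lower around a median of all genes of -0.14, and with no between-array normalization 119 and 597 around -0.189. The number of genes called in the same direction in each line, 254, was 146 without A2780 hyperthermia 1, 156 without A2780 hyperthermia 2, 142 without SKOV3 control 1 and 144 without SKOV3 control 2.

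**Figure D3:**
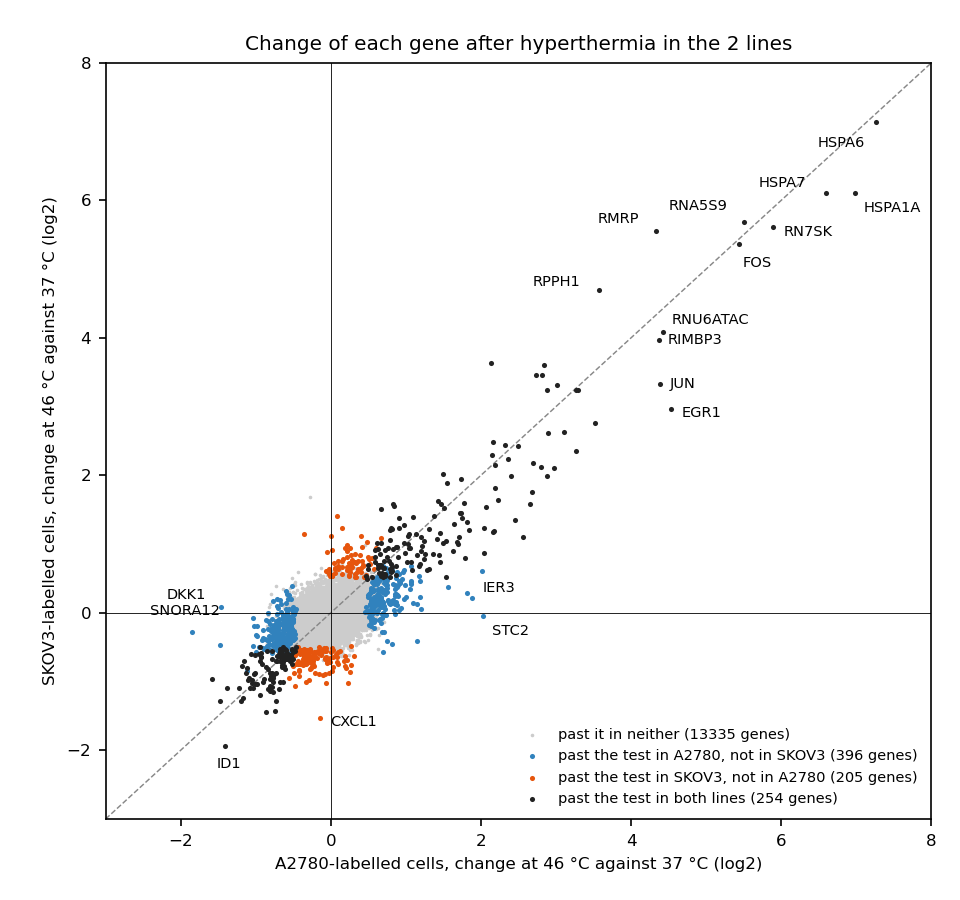
Log2 change of each of 14190 genes at 46 °C against 37 °C in A2780 (horizontal) and SKOV3 (vertical), coloured by the lines in which it passed the test, with a dashed line of equal change. The 254 genes past the test in both lines lie in the quadrants of equal sign, while 396 passed in A2780 and not in SKOV3 and 205 in SKOV3 and not in A2780.

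The next comparison tested the difference itself, as the SKOV3 response minus the A2780 response. The STC2 transcript went from 8.31 to 10.34 in A2780 and from 8.71 to 8.65 in SKOV3, a difference of -2.09 ± 0.20 (adjusted p = 0.000899). IER3, a stress-responsive survival gene, went from 8.72 to 10.60 and from 8.51 to 8.72 (-1.67 ± 0.19, adjusted p = 0.00245). CITED2, a co-regulator of CBP/p300, differed by -1.57 ± 0.20, EGR1 by -1.57 ± 0.18, TSC22D3 (GILZ) by -1.53 ± 0.22, DHDH by -1.46 ± 0.19, CHAC1 by -1.42 ± 0.22 and JUN by -1.05 ± 0.18, with adjusted p from 0.00264 to 0.0459. EGR1 and JUN rose in both lines and started higher in SKOV3, at 9.05 and 7.83 against 7.56 and 5.99 in A2780. In the other direction DKK1 differed by 1.55 ± 0.17 (adjusted p = 0.00245), SNORA12 by 1.58 ± 0.25 (0.0253), RGS16, a regulator of G-protein signalling, by 1.50 ± 0.22 (0.0169) and the cyclin-dependent kinase inhibitor gene CDKN1A by 1.32 ± 0.19 (0.0169). DKK1 fell from 12.86 in A2780, but in SKOV3 it was not above background at 37 °C, where a fall could not be measured, and SNORA12 started at 6.49 there against 8.58 and ended at background. DHDH and JUN were not above background in A2780 at 37 °C, nor CHAC1 in SKOV3. One of the responses compared is then only a lower bound, and the size of these differences is uncertain. CDKN1A went from 10.15 to 10.23 in A2780 and rose from 6.67 to 8.07 in SKOV3 (1.40 ± 0.14), but another CDKN1A probe gave a difference of -0.73 and an SKOV3 change of 0.31 (adjusted p = 0.295).

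Among the lists, histone genes had a median difference of -0.39 (adjusted p = 4.21e-06) with no member past the test (0 and 4 adjusted over the list alone), immediate early genes one of -0.35 (adjusted p = 1.01e-05) with 3 members, IER3, EGR1 and JUN (1 and 12 over the list alone), and ATF4 targets one of -0.05 with a mean of -0.27 (adjusted p = 0.0312) with 2 members, STC2 and CHAC1 (0 and 4 over the list alone). None of the 3 passed with an estimated correlation (adjusted p = 0.613 for each). With no between-array normalization the medians were 0.101, 0.068 and 0.332, and with median scaling that of the ATF4 targets was 0.218, although all 3 stayed below the median of all genes. The ATF4 list lost its call without A2780 control 1 (adjusted p = 0.379), without SKOV3 control 2 (0.191) and without SKOV3 hyperthermia 2 (0.224), in a range of 0.000676 to 0.613 over all alternatives. It was lost too with the authors' values (0.0665), the floor (0.0606), median scaling (0.147) and no between-array normalization (0.114). The remaining 30 lists did not pass (adjusted p from 0.0652 to 0.969).

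The response of 17 genes differed, 4 more positive and 13 more negative in SKOV3, and 1214 genes had an unadjusted p under 0.05 (710 by chance). The count was 119 without A2780 control 1, 11 without A2780 control 2, 4 without A2780 hyperthermia 1, 7 without A2780 hyperthermia 2, 3 without SKOV3 control 1 and 4 without SKOV3 control 2. With median scaling 10 genes were more positive and 2 more negative, around a median of all genes of 0.271, and with no between-array normalization 7 and 1, around 0.385. STC2 and DKK1 passed under all alternatives run (adjusted p up to 0.0252 and 0.0459), whereas IER3 and EGR1 lost their calls under both of these scalings, IER3 with an adjusted p of 0.0674 and 0.0933 and EGR1 with 0.0578 and 0.0933, as did CITED2, TSC22D3, CHAC1 and JUN. EGR1 lost its call without SKOV3 control 1 as well (0.052). Leaving out A2780 hyperthermia 1, SKOV3 control 1 or SKOV3 control 2 ended the calls of CITED2 (adjusted p = 0.0951, 0.0787 and 0.0879), DHDH (0.0897, 0.087 and 0.0553), TSC22D3 (0.16, 0.172 and 0.0879), CHAC1 (0.177, 0.099 and 0.236), RGS16 (0.16, 0.181 and 0.132), SNORA12 (0.117, 0.247 and 0.23), CDKN1A (0.16, 0.14 and 0.193) and JUN (0.16, 0.352 and 0.236). Without A2780 hyperthermia 2 the calls of CHAC1 (0.17), RGS16 (0.0985), SNORA12 (0.211), CDKN1A (0.0985) and JUN (0.25) were lost, without A2780 control 2 those of CDKN1A (0.068) and JUN (0.259), without SKOV3 hyperthermia 2 those of CHAC1 (0.0617), SNORA12 (0.0617) and JUN (0.0689), and without SKOV3 hyperthermia 1 that of JUN (0.0798). With the authors' values SNORA12 (0.105), RGS16 (0.105), CDKN1A (0.0922) and JUN (0.349) lost their calls, as they did with a floor in place of the background correction (0.1, 0.1, 0.0907 and 0.338). Both left 1 gene more positive and 11 more negative. The replicate number as a block ended the calls of CHAC1 (0.0561) and JUN (0.0856). The stricter filter (0.0555) and the trended prior (0.0599) ended that of JUN, and no between-array normalization that of DHDH (0.0719). Over all alternatives the adjusted p ran from 0.00101 to 0.0933 for IER3, 0.00113 to 0.0933 for EGR1, 0.00236 to 0.112 for CITED2, 0.0027 to 0.0897 for DHDH, 0.00174 to 0.172 for TSC22D3, 0.00391 to 0.236 for CHAC1, 0.00203 to 0.181 for RGS16, 1.11e-05 to 0.247 for SNORA12, 0.00452 to 0.318 for CDKN1A and 0.0314 to 0.352 for JUN.

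**Figure D4:**
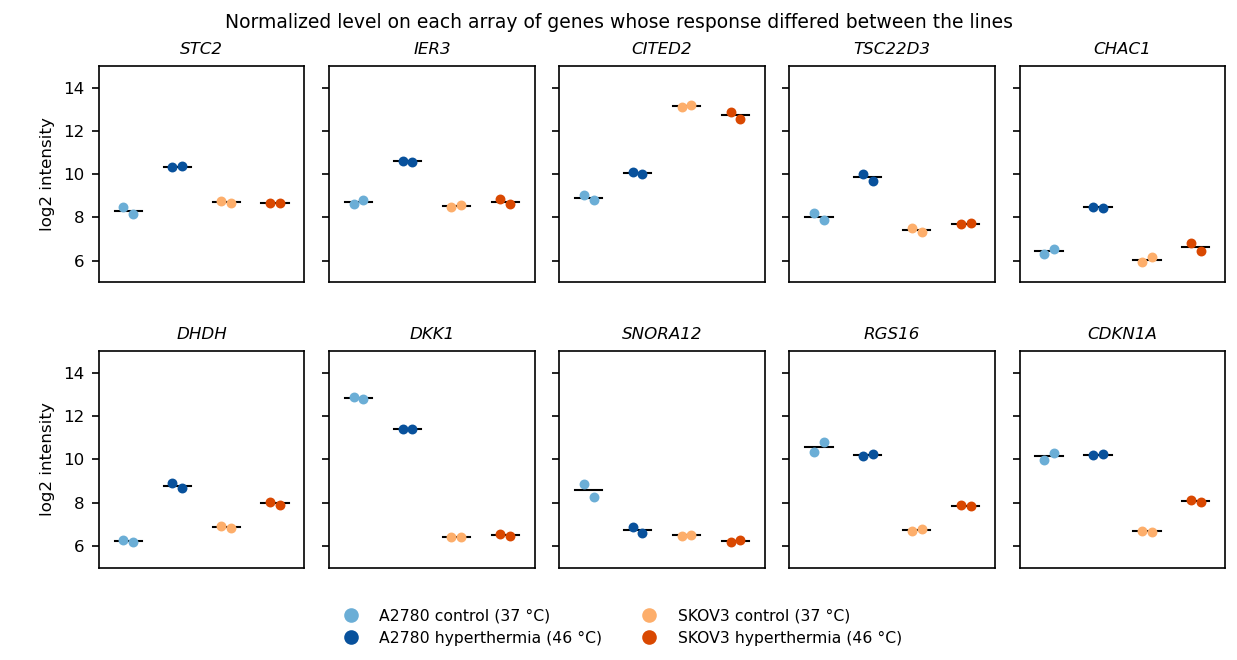
Normalized log2 intensity of 10 genes whose response differed between the lines, on each of the 8 arrays (points) with the group means (bars). STC2 went from 8.31 to 10.34 in A2780 and from 8.71 to 8.65 in SKOV3, and DKK1 fell from 12.86 to 11.39 in A2780 while it was at 6.42 and 6.51 in SKOV3.

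The last comparison set SKOV3 against A2780 at 37 °C, the starting state of the lines. CAVIN2, a caveolar coat protein gene, was at least 93.1-fold higher in SKOV3 (6.75 ± 0.15), the YAP target ANKRD1 at least 64.6-fold (6.38 ± 0.17), the tight junction gene CLDN1 at least 42.8-fold (5.81 ± 0.15), the ubiquitin ligase gene MID1 at least 51.3-fold (5.78 ± 0.14), P3H2 at least 42.0-fold (5.57 ± 0.13) and the growth factor gene NRG1 at least 37.6-fold (5.52 ± 0.13), since all 6 were not above background in A2780. Another MID1 probe gave -0.077 and DBNDD2 (5.08 ± 0.14) was 0.28 at another probe. The transcription factor gene ISL1 (6.02 ± 0.14), the matrix gene POSTN (5.04 ± 0.16) and ARHGAP15 (4.92 ± 0.12) were higher as well. Lower in SKOV3 were ITM2A (-6.45 ± 0.17, at least 68.9-fold), DKK1 (-6.43 ± 0.12, at least 84.5-fold), the proteoglycan genes DCN (-5.90 ± 0.14, at least 54.7-fold, another probe -0.019) and LUM (-5.89 ± 0.14), the matrix link protein gene HAPLN1 (-5.74 ± 0.14, at least 41.7-fold), the calcium-binding protein gene S100A4 (-5.72 ± 0.13), the neuropeptide genes VIP (-5.43 ± 0.14, at least 31.2-fold) and NTS (-5.10 ± 0.16), the transcription factor gene SNAI2 (-5.34 ± 0.14, at least 35.45-fold) and the melanosomal enzyme gene TYRP1 (-4.96 ± 0.14, at least 23.3-fold), the bounds standing where SKOV3 was not above background. The adjusted p of these 20 genes was at most 3.13e-11.

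Mesenchymal genes were lower as a list in SKOV3: 13 of 22 were lower and 2 higher (list adjusted p = 4.17e-06, and adjusted p = 0.144 with an estimated correlation). S100A4, SNAI2, TWIST1 (-4.28 ± 0.17) and the collagen gene COL3A1 (-4.16 ± 0.17) led them. Of 10 fibroblast and stroma markers 7 were lower and 1, POSTN, higher (list adjusted p = 4.49e-05, and adjusted p = 0.194 with an estimated correlation), and 9 of them lay above background in the A2780 controls against 3 in the SKOV3 controls. Of 16 interferon-stimulated genes 7 were higher and none lower (list adjusted p = 0.0142, and adjusted p = 0.285 with an estimated correlation), with ISG15 at 2.17 ± 0.13, IFITM1 at 2.01 ± 0.14, IFI6 at 1.80 ± 0.13 and HERC5 at 1.41 ± 0.17. With no between-array normalization the median of the list was -0.027, which is above the median of all genes there, -0.351. Of 5 metallothioneins, near-identical copies, 4 were higher (list adjusted p = 0.0166, and adjusted p = 0.285 with an estimated correlation), namely MT2A (1.48 ± 0.12), MT1X (0.79 ± 0.14), MT1G (0.52 ± 0.17, at least 1.19-fold) and MT1F (0.46 ± 0.14). Of 16 ER chaperones 7 were lower and 1 higher (9 and 1 adjusted over the list alone, list adjusted p = 0.0395, and adjusted p = 0.285 with an estimated correlation), with HSPA5 at -1.67 ± 0.15, calnexin (CANX) at -1.14 ± 0.14, PDIA4 at -0.91 ± 0.15 and PDIA6 at -0.85 ± 0.20. The remaining 27 lists did not pass (adjusted p from 0.0647 to 0.956). Epithelial genes were among them at 0.0647, with 3 higher, CLDN1, KRT18 (1.82 ± 0.16, at least 2.71-fold) and EPCAM (1.23 ± 0.16), and ELF3 lower (-0.83 ± 0.21).

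The calls of metallothioneins and ER chaperones were fragile: the former was at 0.0557 without A2780 control 1 (range of adjusted p over alternatives 0.00332 to 0.285), the latter at 0.0502 without SKOV3 control 1 (range 0.00724 to 0.285). The former was also lost with no filter (0.0932), the latter with the stricter filter (0.0597), a filter on background (0.0675) and the 37 °C arrays alone (0.051). MT1G lost its call without A2780 control 1 (0.084), A2780 control 2 (0.103) and SKOV3 control 1 (0.377), MT1F without A2780 control 1 (0.221), SKOV3 control 1 (0.0847) and SKOV3 control 2 (0.154), and ELF3 without A2780 control 2 (0.0991) and SKOV3 control 1 (0.0811). Their ranges over all alternatives were 0.00626 to 0.377 for MT1G, 0.00926 to 0.419 for MT1F, 0.000202 to 0.689 for MT1X and 0.00011 to 0.0991 for ELF3. MT1X lost its call with median scaling (0.32) and with no between-array normalization (0.689). MT1F and MT1G lost theirs with the authors' values (0.0533 and 0.073) and with the floor (0.0519 and 0.0716) too. In all, 2202 genes were higher and 1950 lower in SKOV3, 563 and 443 of them at least 2-fold, and 5475 had an unadjusted p under 0.05. The count was 2567 without SKOV3 control 1 and 2678 without SKOV3 control 2. With median scaling 794 genes were higher and 4815 lower, around a median of all genes of -0.229, and with no between-array normalization 563 and 5470, around -0.351.

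As a check of the labels, HSPA1A, HSPA1B and DNAJB1 were higher on both 46 °C arrays than on both 37 °C arrays of each line. ERBB2, which is known to be amplified in SKOV3, lay at 9.41 in the A2780 controls, 9.07 after 46 °C, 9.51 in the SKOV3 controls and 9.32 after 46 °C. Its difference between the lines at 37 °C was 0.10 ± 0.13 (adjusted p = 0.635), and it was -0.445 with median scaling, -0.567 with no between-array normalization (lower in SKOV3 with an adjusted p of 0.035, in a range of 0.035 to 0.955 over all alternatives), -0.017 without A2780 control 1 and 0.223 without A2780 control 2. The median of all genes was -0.229 with median scaling and -0.351 with no between-array normalization, so a large part of the ERBB2 values there is the shift of all genes. The keratin genes KRT7 and KRT8 and the cadherin gene CDH1 were not above background on any array, and 3 of the 4 SKOV3 arrays had KRT19 above it. KRT18 and EPCAM were above background on all 4 SKOV3 arrays, and KRT18 on no A2780 array. The names A2780 and SKOV3 stand throughout for the labels.

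**Figure D5:**
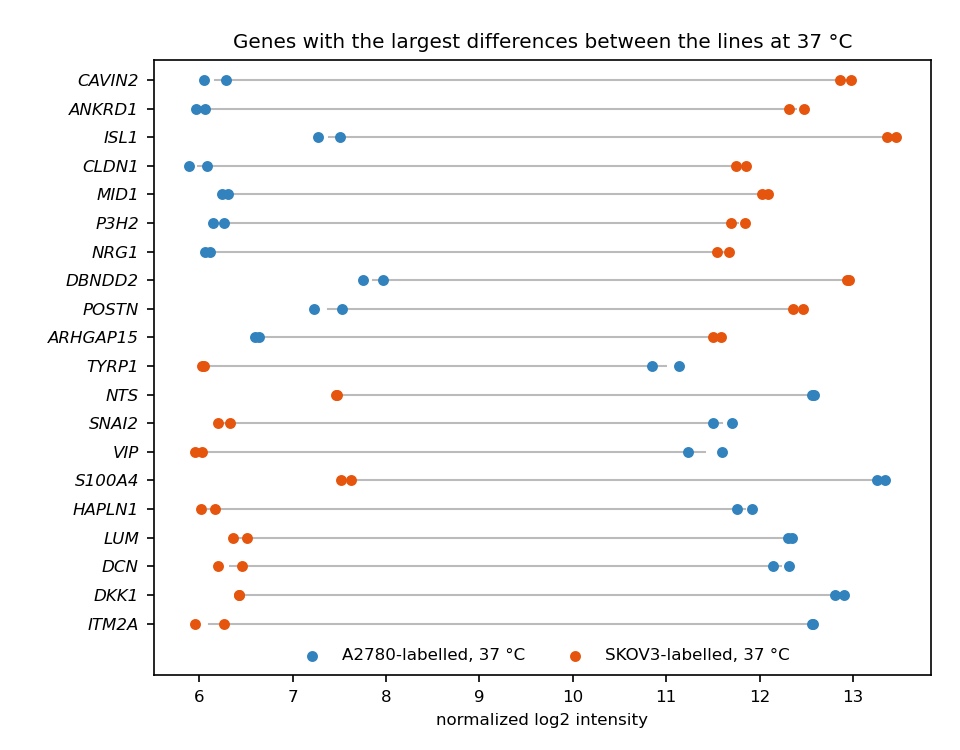
Normalized log2 intensity at 37 °C of the 20 genes with the largest differences between the lines, on the 2 control arrays of each line (points, joined by a line between the group means). CAVIN2 was at 6.17 in A2780 and 12.92 in SKOV3, and ITM2A at 12.56 and 6.11.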

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

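The tests of a difference between the lines were set before the data were examined; the count of probes without a gene name was chosen after. The 12 genes below were singled out because the test of the difference itself found that their responses to 46 °C were unlike in A2780 and SKOV3, and 17 genes in all met that test. On the log2 scale the SKOV3 response minus the A2780 response was 1.575 for SNORA12, 1.55 for DKK1, 1.50 for RGS16 and 1.32 for CDKN1A, and -2.09 for STC2, -1.67 for IER3, -1.57 for CITED2, -1.57 for EGR1, -1.53 for TSC22D3, -1.46 for DHDH, -1.42 for CHAC1 and -1.05 for JUN. Of these, STC2 and DKK1 passed under all alternatives run, but DKK1 was not above background in SKOV3 at 37 °C, so its difference is the A2780 fall set against a floor. Another CDKN1A probe gave -0.728, and DHDH and JUN in A2780 and CHAC1 in SKOV3 were not above background at 37 °C, which leaves the size of their differences uncertain. Leaving out single arrays left between 3 (without SKOV3 control 1) and 119 (without A2780 control 1) genes called.

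The same test over lists singled out the histone genes, with a median difference of -0.391, the immediate early genes, with -0.346, and the ATF4 targets, with -0.049, each lower in SKOV3 relative to all genes. None of these 3 lists passed with an estimated correlation between genes (adjusted p = 0.613).

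Among 8791 probes above the filter that the annotation pairs with no single gene, which the comparisons left aside, 158 were higher and 93 lower at 46 °C than in the controls of A2780, and 92 were higher and 69 lower in SKOV3. Of these, 41 were higher in both lines, with rises of up to 3.82 in A2780 and 3.84 in SKOV3, and 24 were lower in both.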

How the results depend on the processing

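Alternatives described as added were chosen after the data were seen; the others were planned. Counts of called genes and of lists stayed within 1.5 times their values except as follows, and the cause was not tested unless given. With the authors' values 2 lists passed in SKOV3, with the floor 3, with the stricter filter 2, and with the added background filter 2. With median scaling the counts were 4584 in A2780, 265 in SKOV3 and 10 lists between the lines at 37 °C, and with no between-array normalization 5311 in A2780, 192 in SKOV3, 8 in the difference and 139 shared by the lines; here the median of all A2780 changes moved to -0.28 and -0.385. With no filter 29 genes differed in response, and with array weights 26, with 1533 in the common response. A minimum of 2-fold, a narrower criterion by construction, left 141 genes in A2780, 125 in SKOV3, 1006 at 37 °C, 116 common and 83 shared. With an estimated correlation 2 lists passed in A2780, 2 in SKOV3, 0 in the difference and 0 at 37 °C. The added crossed block gave 30 genes in the difference, and the added median scaling without A2780 control 2 gave 1689 in A2780, 33 in the difference and 5 lists in the difference. Including the probes without a name, also added, left 890 and 594 calls in the lines, within 1.5 times the values reported.

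Leaving out single arrays, where the lone sample of a group was assumed to vary like the other groups, gave 242 to 1146 genes in A2780, 174 to 587 in SKOV3, 3 to 119 in the difference, 2567 to 4487 at 37 °C, 561 to 1124 in common and 142 to 251 shared, and 5 to 8, 2 to 5, 2 to 4 and 5 to 7 lists in A2780, in SKOV3, in the difference and at 37 °C. Of 3262 values of 146 named gene results under these alternatives, 3098 kept their direction and side of the threshold, 155 kept their direction and lost their call, and 9 reversed. The named genes were chosen mostly among the largest changes past the test, so these numbers do not describe the called genes as a whole. ERBB2 at 37 °C was -0.445 with median scaling, -0.567 with no between-array normalization, -0.145 with the added median scaling without A2780 control 2 and -0.017 without A2780 control 1, against 0.223 without A2780 control 2. The median of all genes at 37 °C was -0.229 with median scaling and -0.351 with no between-array normalization. Other probes reversed D2HGDH in A2780 (0.057) and in common (0.015), MID1 at 37 °C (-0.077), CDKN1A in the difference (-0.728) and ZNF626 in A2780 (-0.174). Genes near background, such as HSPA1A and RMRP at 37 °C, have only a lower bound to their fold, and HSPA1B lies near the highest normalized value.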

Other observations

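The tests of the mRNA share, of RNA polymerase III, of the ERBB2 level and of weak mRNAs were chosen only after the result was seen; those of the normalization, of A2780 control 2, of gene span and of other splits of the samples were set before their results. The class of structural noncoding RNAs was itself gathered after the largest rises had been seen, and it counts copies that share probe signal as separate genes. Its p-values therefore describe the class and are not an independent test of it. Of its 29 tested members (spliceosomal and 7SK RNAs, ribosomal, Y and vault RNAs, the RNAs of RNase P and RNase MRP and others) 24 rose in A2780 (82.8%, against 2.1% of the other genes; two-sided Fisher's exact test, adjusted p = 1.25e-34 over 10 classes) and 20 in SKOV3 (69%, against 1.4%; adjusted p = 2.38e-29), and none fell. Their median change was 2.22 and 1.75, and camera with an estimated correlation gave p = 0.00198 and 0.00257. All 3 ribosomal RNAs rose in both lines, with RNA18SN5 at 2.68 ± 0.13 and 1.75 ± 0.13 and RNA28SN5 at 1.64 ± 0.13 and 1.29 ± 0.13, though RNA28SN5 reached 14.13 and 14.05, near the highest normalized value, where a change can be compressed. Among the spliceosomal and related small nuclear RNAs 14 of 15 rose in A2780 and 10 in SKOV3, including RNU1-1 (3.02 ± 0.15 and 3.31 ± 0.15), whose copies share probe signal, and RNU6-1 (2.40 ± 0.17 and 2.00 ± 0.17). RN7SL1, the RNA of the signal recognition particle, stood at 0.29 ± 0.14 and -0.02 ± 0.14 and RNY3 at 0.32 ± 0.13 and -0.30 ± 0.13, neither past the test, and RN7SL1 lay between 13.43 and 13.74 throughout, also high on the scale.

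As technical explanations of the rise of structural noncoding RNAs, a lower share of mRNA in the labelled RNA would raise other RNAs without a poly(A) tail alike, but the 109 small nucleolar RNAs above background at 37 °C had medians of 0.12 in A2780 (95% bootstrap interval 0.02 to 0.25) and 0.06 in SKOV3 (-0.06 to 0.20). Some small nucleolar RNAs did rise, 31 of 213 in A2780 (14.6%, against 2.1% of other genes) and 25 in SKOV3 (11.7%, against 1.4%), while 11 and 9 fell, so the medians argue against a lower mRNA share only as the whole cause. The between-array normalization is argued against by medians of 1.73 and 1.91 without it, and the A2780 control 2 array by a median of 2.11 in A2780 without that array. Transcription by RNA polymerase III could not be settled: the 15 members it transcribes had a median of 2.46 and the 12 transcribed by RNA polymerase II 1.15, a difference of 1.32 with a permutation p of 0.28 (two-sided, 100000 permutations). A change in the processing, polyadenylation or breakdown of these RNAs at 46 °C, which would let more of them be labelled, stays open as a hypothesis and was not tested.

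ERBB2 did not pass the test between the labels, although it is known to be amplified in SKOV3. With no between-array normalization it was lower in SKOV3 (-0.567, limma adjusted p = 0.035), but the median of all genes was then -0.351, so a large part of that value is the shift of all genes. The values leave the technical explanations open. Labels exchanged between the lines cannot be told apart from correct ones by the difference of 0.10 ± 0.13, because that difference is the observation itself and no further probe shows that the level is measured: 0 other ERBB2 probes lay above background on all arrays, so a probe that does not respond to the level stays open too. A mislabelled or misidentified line also stays open, because the epithelial markers on the arrays labelled SKOV3 gave mixed readings. Of KRT7, KRT8 and KRT19, 3 of 12 readings were above background, against 8 of 12 of KRT18, CDH1 and EPCAM. KRT7, KRT8 and CDH1 were at background under both labels, so they do not tell the lines apart, and probes that do not respond stay possible for them too. KRT18 and EPCAM were higher on the arrays labelled SKOV3 than on those labelled A2780, which alone does not decide between these explanations. No biological explanation, such as a subline that lost the amplification, was tested.

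Protein-coding genes that fell in both lines (96 genes, median changes -0.76 and -0.73) spanned a median of 13.6 kb of the genome, against 30.3 kb for 960 genes of matched level that did not pass, a ratio of 0.45 (95% bootstrap interval 0.30 to 0.63; permutation p = 1e-05, the smallest that 100000 permutations can give). That is consistent with decay of short-lived mRNAs, often from short genes, while transcription is lowered. The 100 genes that rose in both lines were shorter still, at 7.5 kb against 32.4 kb (ratio 0.23, interval 0.15 to 0.36), so short span goes with change in either direction and does not single out decay; no half-lives were measured. Of the 96 genes that fell, 92 (95.8%) were still above background on all 4 arrays at 46 °C. That argues against loss to background for these genes only. The 96 genes had a mean level of 9.48 at 37 °C, against 8.25 for the other protein-coding genes. Genes near background could hardly enter a set chosen for its falls, so loss of weaker mRNAs was not tested.

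The 999 genes of the common response changed on average over the lines, and not all of them were called in each line. For them, the 18 splits of the 8 samples with 2 of each line on either side are too few for a share under 0.05. Among them 1, the real one, gave as many genes, and the highest of the others gave 0. At an unadjusted p under 0.05 the real split gave 2880 genes and the highest of the others 1458.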
